A study of Mus musculus with 4 samples.

How the data were processed

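RNA expression was measured in whole testes of male mice at postnatal day 9, with 1 control array and 3 Dmrt1 knockout arrays. Per the labels' protocols, total RNA was extracted with TRIzol, cleaned on a column, checked on a Bioanalyzer, reverse transcribed, labelled with the dye Cy3 and hybridised to a one-colour NimbleGen expression array. The control was labelled Cre-negative and the knockouts Cre-positive, and the titles name the DHH-cre driver. The labels do not say whether the 3 knockout arrays came from separate animals, so the p-values measure only the spread between these samples, which may be technical.

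The deposited values were intensities on a linear scale, 1 per RefSeq transcript and array, made by the authors with RMA per the submitters' processing notes. RMA is a method that corrects background, normalises arrays to a common distribution by quantiles and summarises several probes per transcript. The version of RMA, the background settings and the probes behind each transcript were not given in the sources used here. The table held 25631 transcripts with no gene names, detection calls or background columns, so no transcript could be called below background. Intensities ran from 23.9 to 65156, and the medians of the 4 arrays lay between 1005 and 1011. Of the values above 1000, 28.8% lay on a grid of 0.25 intensity units within 0.0001. The number of arrays limits the precision, and no measure of scanner signal over background was used here.

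All values were above the floor of 1 set before the data were examined, and log2 was taken. Gene symbols were assigned by matching transcript accessions without version to a RefSeq gene table of assembly GRCm38.p6, which named 17780 transcripts (69.4%) and 17277 genes. The other 7851 transcripts, 6733 with XM and 1118 with NM accessions, stayed without a name. The array was designed on an older assembly, so no coordinates are printed and the table served for names, chromosomes and the order of neighbouring genes. For the 433 genes with over 1 transcript, the transcript with the highest mean over the 4 arrays stood for the gene.

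Each transcript was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with a knockout minus control coefficient, two-sided, and Benjamini-Hochberg adjustment over all 25631 transcripts. A transcript passed at an adjusted p under 0.05. The design left 2 residual degrees of freedom, to which the prior added 7.97. The spread came from the knockout arrays alone, so the lone control was assumed to vary like them, and any peculiarity of that array counted as a difference of the group. Standard errors are those of the moderated fit. Transcripts at least 2-fold apart between the control and each knockout array were counted as well, with no p.

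The 23 gene lists were fixed from textbook knowledge. They covered the DM domain family, Sertoli cells, granulosa and ovarian somatic cells, undifferentiated spermatogonia, differentiating spermatogonia, meiosis, germ cells of all stages, Leydig cells and steroidogenesis, cholesterol synthesis, peritubular myoid and smooth muscle, macrophages, endothelium, erythroid cells, skeletal muscle, adipose tissue, epididymis and ducts, the retinoic acid pathway, cell junctions of the seminiferous epithelium, the cell cycle, cyclin-dependent kinase inhibitors, immediate early and heat shock genes, housekeeping genes and a sex check. Of their 376 genes, 340 were measured, and 1 older symbol was updated. The 22 lists with at least 5 measured genes were tested with limma's camera at a preset correlation of 0.01, Benjamini-Hochberg adjusted over the lists. Camera with an estimated correlation, camera on ranks and limma's fry were run beside it. With an estimated correlation, camera rests on the 2 residual degrees of freedom, so few lists could pass it whatever their correlation.

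The text names Dmrt1, then the 10 genes with the largest difference in each direction among those that passed with every knockout array on one side. It also names up to 4 members of each list with the smallest p, and Foxl2, Sox9, Sox8, Amh, Kit, Stra8, Ret, Gfra1, Cyp17a1, Hsd17b3 and Dhh. Unnamed, RIKEN and predicted genes were skipped in filling the 10. Genes outside this rule are said to have been chosen after their values were seen. The groups, tests, lists, naming rule and alternatives were chosen before the data were examined. The alternatives left out each knockout array, normalised or centred the arrays again, removed the dimmer transcripts, averaged the transcripts of a gene, changed the variance prior or changed the threshold.

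The procedure was tested on simulated data for the comparison of 1 control with 3 knockout arrays over 25631 transcripts. It recovered 2 of 50 transcripts changed by 1 on the log2 scale, 19 of 50 at 1.5, 43 of 50 at 2 and 50 of 50 at 3, and called 3 of 25431 unchanged transcripts. With nothing changed, the median over 20 draws was 0 calls when the control varied like the knockouts, 6.5 calls when its SD was 1.5 times theirs and 1340 calls when it was 2 times theirs. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.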

Results

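Gene expression was compared between 1 control testis array and 3 arrays labelled Dmrt1 knockout, all from mice at postnatal day 9. Dmrt1 encodes a DM domain transcription factor of Sertoli cells and germ cells. Desert hedgehog is made by Sertoli cells, the somatic cells that enclose the germ cells, and its Cre driver served to delete Dmrt1. The comparison asks how expression in the juvenile testis differs when Dmrt1 is conditionally deleted. Across transcripts, which are not independent replicates, Pearson's r between log2 levels of array pairs was 0.981 to 0.986 for the control with each knockout and 0.986 to 0.989 among the knockouts. Knockout replicate 3 stood apart from the other knockouts. The interquartile spread of its log2 differences, scaled to an SD, was 0.319 from the control, the smallest of the 6 pairs, against 0.368 and 0.373 from knockout replicates 1 and 2. The full SD of these differences gave another order, at 0.424 from the control and 0.418 and 0.412 from replicates 1 and 2. Pearson's r did too, at 0.9858 with the control and 0.9862 and 0.9866 with these replicates. On the first principal component (45.9% of the variance) knockout replicate 3 lay at -7.00, between the control at -43.8 and the other knockouts at 21.1 and 29.7, and on the second (29.4%) at 36.6, against -15.6 for the control and -23.0 and 1.95 for the other knockouts.

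Dmrt1 itself (NM_015826) had a log2 intensity of 14.16 in the control and of 13.23, 13.38 and 13.66 in the 3 knockout arrays. The difference was -0.73 ± 0.27 (SE, 1 control and 3 knockout arrays), a level 1.66-fold lower in the knockouts. It did not pass limma's test (adjusted p = 0.586, unadjusted p = 0.0236). All 3 knockout arrays lay below the control. The position of the probes relative to the deleted part of the gene is not known here, and a probe outside that part would not check the labels. Germ cells also express Dmrt1 and contribute to whole-testis RNA, so the value is not the level in Sertoli cells.

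In the knockout arrays, 90 named genes fell and 34 rose. The genes that fell included Slco1a5, an organic anion transporter, by 27.6-fold, and Gja6, a connexin, by 18.5-fold. Frzb, a secreted Wnt antagonist, fell 14.5-fold and Enpp2, the enzyme that makes lysophosphatidic acid, fell 12.1-fold. The genes that rose included Mybphl, a myosin-binding protein homolog, by 8.20-fold, H2-Eb1, an MHC class II chain, by 6.25-fold, and Wif1, a secreted Wnt inhibitor, by 4.65-fold. By transcript, limma called 168 of 25631, with 128 lower and 40 higher, so 76.2% of the calls were lower. Every call had the 3 knockout arrays on one side of the control. The smallest called difference was 1.35 on the log2 scale, and the median fold was 4.66 for lower and 3.73 for higher transcripts.

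Slco1a5 (NM_130861) fell from an intensity of 1384 in the control to 50.3 ± 3.81 (SD, n = 3). The difference was -4.79 ± 0.26 on the log2 scale (limma, adjusted p = 3.76e-05). With no background values used here, it is not known whether levels this dim lie above background, so the folds and the order of genes that fell to such levels, Gja6 and Frzb among them, are uncertain. The same holds for genes that rose from dim levels, such as H2-Eb1, with a control intensity of 85.8. Rnf138rt1 differed by -4.54, Gja6 by -4.21, Vsig1 by -3.91, Frzb by -3.86 and Slc47a2, a drug and toxin exporter, by -3.70. Enpp2 differed by -3.60, Nxf3 by -3.48, Cdo1, a cysteine dioxygenase, by -3.40 and Tspan17, a tetraspanin, by -3.24. Rnf138rt1, Gja6, Vsig1 and Nxf3 are X-linked in the annotation, as were 21 of the 90 genes that fell. The standard errors of these 10 ran from 0.25 for Nxf3 to 0.43 for Cdo1, and the highest adjusted p was 0.00496, for Cdo1.

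Mybphl (NM_026831) had the largest rise among the named genes, from an intensity of 548 to 4515 ± 579 (SD, n = 3), or 3.04 ± 0.27 on the log2 scale (limma, adjusted p = 0.000714). Zg16 differed by 2.72, H2-Eb1 by 2.64, AA467197 by 2.64 and Inpp5j, an inositol phosphatase, by 2.44. Pipox, a peroxisomal sarcosine oxidase, differed by 2.42, Adamts16, a metalloprotease, by 2.41, Wif1 by 2.22, Mybpc3, a cardiac myosin-binding protein, by 2.22 and Fam155a by 2.06. The highest adjusted p of these 10 was 0.0330, for Mybpc3. AA467197 no longer passed with a robust variance prior (adjusted p = 0.0608, with a range of 0.00135 to 0.0608 over its alternatives).

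**Figure D1:**
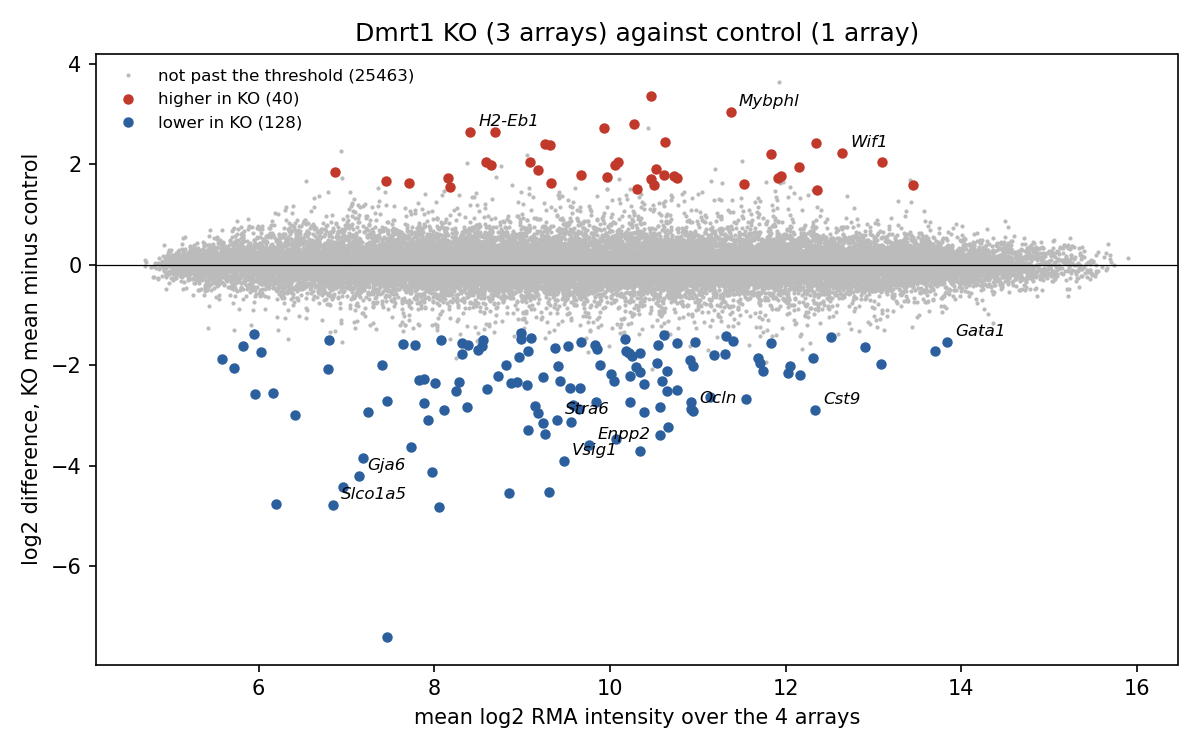
Each point is 1 of 25631 transcripts, with its mean log2 RMA intensity over the 4 arrays on the x axis and the log2 difference, knockout mean minus control, on the y axis. Red points are the 40 transcripts higher and blue points the 128 lower in the knockout arrays at an adjusted p under 0.05, and grey points did not pass; the lowest point is an unnamed transcript at -7.41.

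Without regard to a variance estimate, 193 transcripts were at least 2-fold lower than the control in every knockout array and 102 at least 2-fold higher. The count of higher transcripts was 154 without knockout replicate 1 and 187 without replicate 3, each with fewer arrays that had to meet the bound. The limma count of higher transcripts was 62 without replicate 3, against 40 with all arrays, and 33 of those 40 were among the 62. Of the transcripts without a symbol, 31 were lower and 5 higher. They included XM_889482 at -7.41 and XM_621314 at 3.36.

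Genes of the Sertoli cell list moved in both directions. Cst9, a cystatin, fell 7.43-fold, Defb36, a beta defensin, 4.61-fold and Cldn11, the claudin of Sertoli tight junctions, 3.29-fold, and Krt18, a keratin of simple epithelia, rose 3.32-fold. Gata1, a transcription factor of Sertoli and blood cells that was chosen after its values were seen, fell 2.92-fold. In all, 4 of the 33 measured members fell, 1 rose and 28 did not pass, and adjusted over the list alone 6 fell and 2 rose. The added members were Fshr (-1.12), Tsx (-0.98) and Tesc (1.65), also chosen after their values were seen. Cst9 had a log2 level of 14.50 in the control and 11.61 ± 0.63 (SD, n = 3) in the knockouts (limma, adjusted p = 0.0111).

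Sox9, Sox8, Amh and Dhh did not pass the test. Sox9, a transcription factor of testis determination, differed by -0.56 ± 0.28 (SE), its relative Sox8 by -0.17 ± 0.32, and Amh, anti-Mullerian hormone, by -0.05 ± 0.25. Dhh, the gene of the Cre driver, differed by 0.39 ± 0.25. The median difference of the Sertoli list was -0.08 and the mean -0.17, and camera gave an adjusted p of 0.240. In the same arrays the macrophage and adipose lists had medians of 0.30 and 0.21, with camera calls that were lost with an estimated correlation (adjusted p = 0.886 and 0.735 with an estimated correlation).

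Among the junction genes of the seminiferous epithelium, Ocln, the tight junction protein occludin, fell 7.36-fold and Cldn11 fell 3.29-fold. Ocln had a log2 level of 13.08 in the control and 10.20 ± 0.50 (SD, n = 3) in the knockouts (limma, adjusted p = 0.00495). Gja1, the connexin 43 gene, was at -1.56 ± 0.39 and Jam3, a junctional adhesion molecule, at -0.77 ± 0.25, and neither passed over all genes. Of 17 measured members 2 fell, 0 rose and 15 did not pass, and adjusted over the list alone 3 fell, with Gja1 added. Gja1 passed over all genes without knockout replicate 2 (adjusted p = 0.0484, with a range of 0.0484 to 0.203 over its alternatives). The list's median was -0.20 (camera, adjusted p = 0.0235), and adjusted p = 0.735 with an estimated correlation. That correlation was -0.015, below the preset 0.01, so its size does not explain the loss of the call.

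In the DM domain family, to which Dmrt1 belongs, Dmrta1 and Dmrtc1a fell. Dmrta1 fell 6.70-fold, with a difference of -2.74 ± 0.31 on the log2 scale (limma, adjusted p = 0.00294). The standing transcript of Dmrtc1a fell 3.87-fold, and 2 further transcripts of the gene differed by -4.83 and -4.12. Dmrtc1a and Dmrtc1b are close copies, and the split between them is uncertain on these probes. Dmrtc1b was at -1.20 ± 0.52 and did not pass. The list tested holds both copies and Dmrt1 itself, so its members are not independent and its shift includes the deleted gene. Of 8 measured members 2 fell and 6 did not pass, both over all genes and adjusted over the list alone. The list's median was -0.75 (camera, adjusted p = 0.000254), and adjusted p = 0.735 with an estimated correlation. That correlation was 0.015, near the preset 0.01, so its size does not explain the loss of the call.

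Stra6, the cell-surface receptor that takes up retinol, was the 1 member of the retinoic acid list that passed. It fell 8.51-fold, with a difference of -3.09 ± 0.28 on the log2 scale (limma, adjusted p = 0.000731). Rara, a retinoic acid receptor, was at -0.75 ± 0.25, Rdh10, a retinol dehydrogenase, at -0.53 ± 0.30 and Cyp26a1, an enzyme that degrades retinoic acid, at -1.18 ± 0.44. Of 19 measured members 1 fell and 18 did not pass, also adjusted over the list alone, and camera gave an adjusted p of 0.188.

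**Figure D2:**
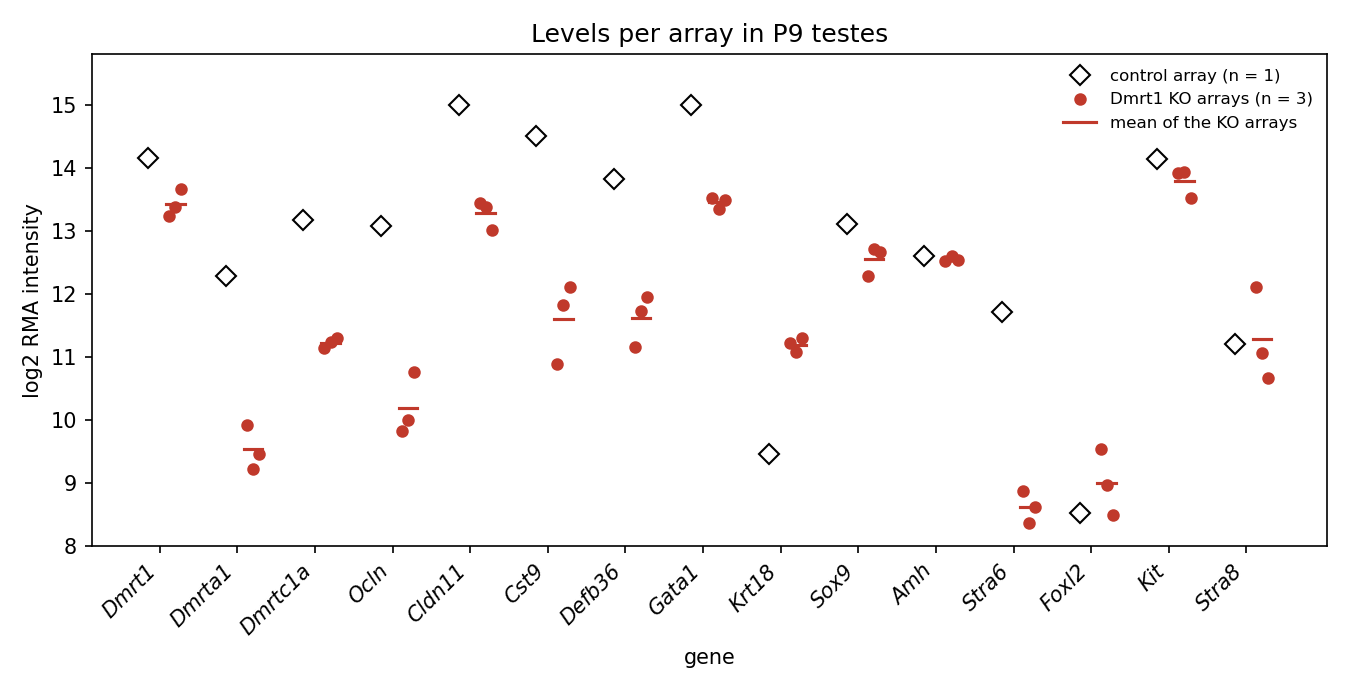
Log2 RMA intensity (y axis) of 15 genes (x axis) in the control array, shown as open diamonds (n = 1), and in the knockout arrays, shown as red points (n = 3) with a bar at their mean. Ocln, Cst9, Defb36, Stra6 and Dmrta1 lie lower and Krt18 higher in every knockout array, and the knockout points of Amh lie at the level of the control.

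No member of the granulosa and ovarian somatic list passed over all genes. Foxl2, the transcription factor that keeps ovarian identity, had a log2 level of 8.53 in the control and of 9.54, 8.97 and 8.50 in the knockouts, a difference of 0.48 ± 0.37 (limma, adjusted p = 0.986). Cyp19a1, the aromatase gene, was at 0.72 ± 0.30, and Nr0b1 was at -1.35 ± 0.26 (adjusted p = 0.0531), Irx3 at -1.87 ± 0.36 (adjusted p = 0.0575) and Lhx2 at -1.44 ± 0.38. These last 3 fell when adjusted over the list alone. limma called 0 of 21 members, with 4 at an unadjusted p under 0.05. Irx3 passed without knockout replicate 2 or 3 (adjusted p = 0.0275 and 0.0095), and with all arrays under the variance trend and the robust prior (0.0367 and 0.0415, with a range of 0.0095 to 0.0652 over its alternatives). Lhx2 passed without replicate 3 (0.0271, range 0.0271 to 0.268), and Nr0b1 passed after quantile normalisation again and with the robust prior (0.0492 and 0.0368, range 0.0368 to 0.105). The list's median was 0.06, its mean -0.12, and camera's adjusted p was 0.641.

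Germ cell genes did not pass in any of the 4 germ cell lists. In simulated data the test recovered only 2 of 50 transcripts changed by 1 on the log2 scale and 19 of 50 at 1.5. An absence of calls, here and in the other lists, therefore does not show an absence of change. Kit, the receptor of differentiating spermatogonia, was at -0.35 ± 0.28 and Stra8, a gene of meiotic entry, at 0.07 ± 0.46. Ret and Gfra1, the receptor pair for GDNF on undifferentiated spermatogonia, were at -0.58 ± 0.43 and -0.51 ± 0.34, and neither passed. The 4 members of that list with the smallest p were Lhx1 at -0.88 ± 0.26, Pou5f1 at 0.89 ± 0.28, T at -0.77 ± 0.26 and Tspan8 at -0.94 ± 0.35. Sohlh1 was at 0.58 ± 0.26, Spo11, which cuts DNA in meiosis, at 0.41 ± 0.33 and Ddx4, a helicase of all germ cells, at 0.25 ± 0.25. Stra8 changed sign without knockout replicate 1, to -0.35.

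By list, limma called 0 of 22 undifferentiated, 0 of 11 differentiating, 0 of 16 meiotic and 0 of 19 pan-germ-cell members, and adjusted over the list alone the counts were also 0. At an unadjusted p under 0.05 the counts were 4, 1, 0 and 0. Camera gave adjusted p-values of 0.240, 0.923, 0.573 and 0.240, and the median differences were -0.08, 0.02, 0.05 and 0.15. The undifferentiated list passed camera, lower, without knockout replicate 3 (adjusted p = 0.0164), with a range of 0.0164 to 0.928 over its alternatives.

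The macrophage and adipose lists passed camera upward at the preset correlation, with no single gene past limma's test. Both calls were lost with an estimated correlation (adjusted p = 0.886 and 0.735 with an estimated correlation) and by directional fry (0.746 and 0.444), and the adipose call also on ranks (0.0580). The estimated correlation was 0.33 for the macrophage list but 0.025 for the adipose list, against the preset 0.01. Ctss, a lysosomal protease, was at 0.71 ± 0.28 and C1qc, a complement subunit, at 0.64 ± 0.26. The macrophage median was 0.30, with 13 of 16 members above 0 (camera, adjusted p = 0.0235). In the adipose list Lpl, lipoprotein lipase, was at 1.71 ± 0.41 and Adipoq, adiponectin, at 0.83 ± 0.29. Its median was 0.21, with 10 of 11 members above 0 (camera, adjusted p = 0.0235). limma called 0 members of either list, with 2 each at an unadjusted p under 0.05, and adjusted over the list alone Lpl rose and no macrophage gene did.

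The macrophage call was lost without knockout replicate 2 (adjusted p = 0.0962) and without replicate 3 (0.0812), with a range of 0.00438 to 0.886 over its alternatives. The adipose call was lost without replicate 1 (adjusted p = 0.0528), with a range of 0.0142 to 0.735. Lpl passed over all genes without replicate 3 (adjusted p = 0.0406, range 0.0406 to 0.200).

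Leydig cell genes, which make testosterone, did not pass singly or as a list. Hsd3b1 was at 0.76 ± 0.26, Cyp17a1 at 0.38 ± 0.39 and Hsd17b3 at -0.57 ± 0.40. limma called 0 of 22 members, also adjusted over the list alone, with 2 at an unadjusted p under 0.05 and a camera adjusted p of 0.0634. The list passed, higher, without knockout replicate 1 (adjusted p = 0.00213), with a range of 0.00213 to 0.886 over its alternatives. The cholesterol synthesis list had a median of 0.15 (0 of 20 called, camera adjusted p = 0.269), with Cyp51 at 0.65 ± 0.25. The peritubular myoid and smooth muscle list had a median of -0.27 (0 of 9 called, camera adjusted p = 0.188), with Acta2, smooth muscle actin, at -0.71 ± 0.26.

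The remaining lists had 0 calls over all genes and adjusted over the list alone. The camera adjusted p was 0.573 for endothelium (12 genes), 0.386 for erythroid genes (6 genes), 0.923 for skeletal muscle (13 genes) and 0.973 for epididymis and ducts (12 genes). It was 0.663 for the cell cycle (22 genes), 0.641 for cyclin-dependent kinase inhibitors (7 genes), 0.641 for immediate early and heat shock genes (15 genes) and 0.641 for housekeeping genes (10 genes). At an unadjusted p under 0.05, the cholesterol list and the cell cycle and kinase inhibitor lists each had 1 member, the myoid list 2 and the others 0; the cholesterol and myoid lists also had 0 calls adjusted over the list alone. The erythroid list passed camera, higher, without knockout replicate 3 (adjusted p = 0.0477), with a range of 0.0477 to 0.928. The sex check list had 4 measured genes, the Y-linked Ddx3y, Kdm5d, Eif2s3y and Uty, below the 5 needed for camera, and limma called 0, with 0 at an unadjusted p under 0.05 and 0 adjusted over the list alone; their differences ran from 0.31 to 0.59.

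By limma's fry, no list passed in one direction, and 5 passed as changed in either direction. These were the Sertoli (adjusted p = 0.0299), junction (0.0299), DM domain (0.0306), immediate early (0.0306) and cholesterol (0.0445) lists.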

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

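Every alternative here was planned before the results were seen. No paired analysis was possible because the labels give no pairing of arrays and there was only 1 control array. Every alternative kept that control array, so none of them varies it. The named genes past the test were chosen for large differences or small p, which favours their staying past it. Of the 28 named genes past the test, all 28 stayed past it in each fit without a knockout replicate, in both further normalisations, with transcript means and with the variance trend, 27 with the robust prior, and 16 of the 16 still tested without the dimmer transcripts, and none changed direction. Of 168 called transcripts, 143 were called in every fit that left out a knockout replicate. Dmrt1 did not pass under any of 11 alternatives (-0.85 to -0.64). Transcripts at least 2-fold higher numbered 123 to 187 over the left-out replicates and those called higher 58 to 62. Without the dimmer transcripts, where fewer were tested, 81 were called lower and 49 higher (52 and 23 of them shared with the 128 and 40), 57 and 87 were at least 2-fold higher and lower, and 2 lists passed. The variance trend called 69 transcripts and 58 genes higher, and a threshold of 0.10 called 75 and 63; why the trend adds calls was not tested. Of the 4 lists past camera, 0 passed with an estimated correlation, 1 on ranks and 0 by fry. With an estimated correlation 0 of all 22 lists passed, and that setting rests on 2 residual degrees of freedom, so it decides little. Over the left-out replicates Slc4a1 ran from -0.0044 to 0.40, Sox8 from -0.29 to 0.049 and Stra8 from -0.35 to 0.37, the sign changing without replicate 1; the cause was not tested. The 4 arrays and the lack of background values limit what can be said of dim transcripts.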

Other observations

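The test of X linkage and the tests of explanations below were chosen after the results were seen. So was the selection of genes in the first 2 paragraphs, apart from H2-Eb1, Mybpc3, Enpp2 and the list members. For a general lowering of X-linked genes and for X-linked neighbouring copies, the predictions were written before those tests were run. Both address an excess among genes that had already been called. Among the genes that rose, H2-Eb1 did so 6.25-fold and Cd74, the MHC class II invariant chain, 4.15-fold. Dsg2 and Dsc2, the cadherins of desmosomes, rose 3.99-fold and 3.60-fold and Eppk1, which binds keratin filaments, 3.12-fold, while Ocln and Cldn11 fell and Krt8 (0.21) and Epcam (-0.43) did not pass. Dsc2 rose from a dim log2 level of 5.49 in the control, so its fold is uncertain. Dsg2, Dsc2, Cd74 and Fhod3 (below) all lie on chromosome 18, so their rises need not be independent. This chromosome held 381 of 17277 measured genes and 4 of the 34 that rose. Chromosomes other than the X were tested only for genes that fell. Mybpc3 rose 4.64-fold and Fhod3, a formin of muscle, 4.13-fold (limma, adjusted p from 0.00132 to 0.0330 for these 7 genes that rose). In the same arrays the macrophage list had a median of 0.30 (camera, adjusted p = 0.0235 at the preset correlation and 0.886 with an estimated correlation).

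Among the genes that fell, Enpp2 did so 12.1-fold and Lpar3, a receptor for its product lysophosphatidic acid, 8.86-fold. Acsl6, which activates fatty acids, fell 6.68-fold, Acss1, which activates acetate, 5.70-fold and Elovl2, which lengthens polyunsaturated fatty acids, 5.61-fold. Vdr, the vitamin D receptor, fell 4.64-fold and Eppin, a protease inhibitor of the male tract, 3.95-fold (limma, adjusted p from 0.000714 to 0.00851 for these 7 genes). The lists with lipid genes did not lie lower: 14 of 20 cholesterol synthesis genes and 10 of 11 adipose genes were above 0, with medians of 0.15 and 0.21. Camera gave adjusted p = 0.269 and 0.0235 at the preset correlation, and 0.886 and 0.735 with an estimated correlation. The genes of these 2 paragraphs were picked singly, no group of them was tested for enrichment, and they stand for no pathway.

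The 168 calls rest on 1 control array. Setting each knockout array alone against the other 3 gave at most 0 calls (881 to 1352 transcripts at an unadjusted p under 0.05, against 1645), and 1 of the 4 splits, the real one, reached 168, but 4 splits are too few for a share under 0.05. In the splits with a knockout array alone, the control was among the other 3. Its differences from the knockouts widened the spread there, so a low count is partly built in. A control array noisier in bulk than the others is argued against by a ratio of 0.993 between its interquartile spread from the knockouts and theirs from each other. That measure leaves out the tails, where the calls lie. The SD of the log2 differences, which counts them, was 0.424 to 0.487 for control pairs and 0.379 to 0.418 for knockout pairs. A loss of Sertoli cells large enough to give the called falls is argued against by the Sertoli list's median of -0.079, with 1 member past the test upward. The rule for this was set after these values were seen, and a smaller loss stays open. A litter, strain or handling difference of the control animal stays open, as does an effect of the deletion. Only the knockouts were labelled Cre-positive, so an effect of Cre or its transgene cannot be told apart from that of the deletion.

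X-linked genes made up 21 of the 90 genes lower in the knockouts (23.3%) but 625 of 17277 measured genes (3.62%). Fisher's exact test gave an odds ratio of 8.35 (95% interval 4.83 to 13.9, two-sided adjusted p = 1.32e-10 over 21 chromosomes), against 1 of 34 higher genes. The test treats genes as independent, but all calls share 1 control array and the 21 genes lay in 14 runs of neighbours. Its p and interval therefore do not measure variation between animals. A general lowering of the X is argued against by a difference of -0.014 between the medians of uncalled X-linked and autosomal genes (95% interval -0.038 to 0.018), and neighbouring copies by an odds ratio of 5.51 with 1 gene kept per run. An X chromosome of another strain in the control stays open: 93.1% of 29 X-linked genes at least 2-fold apart were lower (77.2 to 99.2), which would speak against it only if the probes read both haplotypes alike. No test here separates it from an effect of the deletion or of Cre. That would need further control arrays of the same strain, with Cre-positive controls among them.

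For 28 named genes the arrays fell into pairs, with both arrays of one pair at least 2-fold from both arrays of the other; the control paired with knockout replicate 3 for 18, with replicate 1 for 6 and with replicate 2 for 4. In 4 of them, Cdo1, Mdfic, Paqr8 and Cnmd, the control also lay at least 2-fold to one side of every knockout array, so these follow the groups as well. The 28 formed 6 pairs of neighbours within 50 measured genes, against a mean of 0.967 in 10000 random sets (one-sided permutation p = 0.0008), and the other 24 formed 5 (permutation p = 0.0013). With 1 gene kept per run, which sets aside neighbours such as Zfp456 and Zfp459, 3 pairs were left (permutation p = 0.019), all in 1 cluster of Gadd45gip1, Prdx2 and Tox3 against a mean of 0.547 clusters (permutation p = 0.44), so strain haplotypes and cross-hybridising copies may each contribute and both stay open. A haplotype flanking Dmrt1 stays open too: its window held 1 called gene, Pip5k1b, against a mean of 0.356, and 27.7% of windows held as many.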
